A study of Rattus norvegicus with 8 samples.

How the data were processed

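Total RNA from whole rat brains was measured on 8 short-oligonucleotide rat genome arrays, 1 array per sample. Per the labels, every rat was intubated and the samples fell into 3 groups. The control group held 3 samples from rats that breathed the volatile anaesthetic isoflurane for 3 min. A group of 2 samples came from rats given 2% isoflurane for 1 hr, and a group of 3 samples from rats given 2% isoflurane for 2 hr. The labels mention a saline perfusion straight after the exposure for the control samples only. How the exposed brains were collected is not given in the sources used here. Each label speaks of a rat but none gives an animal number, so the p-values of single genes measure the spread between these samples, part of which may be technical.

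The authors deposited 1 intensity per probe set and array on a linear scale, with 8799 probe sets per array. The software, the scaling target and the detection calls are not given in the sources used here. The 2% trimmed means of the deposited intensities lay between 150.17 and 150.32, a largest difference of 0.106% against a tolerance of 5%, so the columns were used as deposited without further scaling. The 59 spike-in and housekeeping control probe sets were left out of the tests. Values were floored at the 20th percentile of all values, an intensity of 9.1 or 3.19 on the log2 scale, and log2 was taken. A probe set was kept when it lay above the floor on at least 2 of the 8 arrays, which left 7770 probe sets and removed 970. The floor understates changes of dim genes, and where every array of the lower group sat at the floor the fold change is given as a lower bound. The number of arrays limits the precision of every value.

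Probe sets were named through the platform's annotation table. Of the 8740 probe sets that were not controls, 7006 had 1 gene symbol, 308 had several and 1426 had none. Symbols of 6985 probe sets were updated through the gene number to the RefSeq table of assembly GRCr8, which was used for names only, and no coordinates are given because the build behind the array design is not given in the sources used here. The 7770 probe sets tested covered 4367 distinct genes.

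Each comparison was tested with limma 3.58.1 in R 4.3.3. The functions lmFit, contrasts.fit and eBayes with an intensity trend were run on all 8 arrays with 1 mean per group and 1 shared estimate of the spread. Tests were two-sided, with Benjamini-Hochberg adjustment over the 7770 probe sets and a threshold of 0.05. The comparisons were 2 hr against control, 1 hr against control, any exposure (the mean of the 1 hr and 2 hr group means) against control, and 2 hr against 1 hr. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with 1 probe set per gene (the brightest over all arrays) and adjustment over 31 lists. At the preset correlation camera sets the genes of a list against the other genes. Its p-values therefore do not measure how far the list varies between samples. An estimated correlation and limma's fry, which asks whether the genes of a list move on balance one way, were run as alternatives. The 31 lists comprised 21 pathway or gene family lists and 10 marker lists of cell types or tissues that a whole brain dissection can hold. The lists, the groups, the tests, the first set of alternative settings and the rule for named genes were fixed before the data were examined. That rule took, per comparison and direction, up to 12 genes that passed and had no overlap between the groups, filled to 6 by unadjusted p where fewer passed. From each list described it took up to 4 members that passed, over all genes or over the list alone, and otherwise the 2 members with the smallest unadjusted p. Where a gene had several probe sets, readings of the others are given for the genes named outside the lists. List members rest on the brightest probe set of the gene, and only readings with the opposite sign, or those of the genes described at length, are given for them.

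The steps were tested on simulated data. In 20 simulated data sets of 7770 probe sets with 200 changed, limma recovered 47.6% of log2 changes of 2 and 1.12% of log2 changes of 1 for 2 hr against control. For 1 hr against control it recovered 30.4% and 0.672%. The shares were 66.6% and 5.15% for any exposure, and 24.9% and 0.448% for 2 hr against 1 hr. The share of false calls among all calls was 5.12% for 2 hr against control, 6.38% for 1 hr against control, 5.57% for any exposure and 8.92% for 2 hr against 1 hr, above the threshold of 0.05 in each. In 100 simulated data sets with independent genes, camera recovered a shift of 0.5 of a 16-gene list in 95% of sets for 2 hr against control, 75% for 1 hr against control, 100% for any exposure and 84% for 2 hr against 1 hr. Real genes vary together, which these simulations leave out.

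These alternative settings were quantile normalization, median centring, floors at the 5th and 40th percentiles, a pseudocount, no filter and a strict filter, eBayes without the trend or with robust spread, array weights, a fit of only the compared groups, the replicate number as a block, leaving out each array in turn, and for lists the estimated correlation, fry and the mean of all probe sets of a gene. Alternatives chosen after seeing the data were 2 blocks that follow array properties, leaving out the 3 arrays with the highest top values, leaving out the 2 arrays with the highest Pomc, and excluding the pituitary markers from the other lists.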

Results

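The data set held 8 arrays of whole rat brain, 3 from control rats that breathed isoflurane for 3 min, 2 after 1 hr of 2% isoflurane and 3 after 2 hr of 2% isoflurane. The comparisons asked which transcripts differed in the brain after a single longer exposure to the anaesthetic, and whether 1 hr and 2 hr differed. No group without anaesthetic was analysed here, so the control itself is a brief exposure. Correlations between pairs of arrays across all genes ran from 0.876 to 0.97, and no pair of arrays shared more than 70 identical values of the 8740 probe sets, so all 8 were counted as separate samples.

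Several array properties ran across the groups. The highest intensity was 24393 on control replicate 3, 23009 on 1 hr replicate 1 and 37712 on 2 hr replicate 3, and between 3504 and 12445 on the other 5 arrays. These 3 arrays were parted from the other 5 by a gap of more than 0.5 on the log2 scale for 232 probe sets, the highest number of the 56 ways of choosing 3 arrays, whereas the control arrays were parted from the exposed arrays for 11. The mean log2 intensity of the ribosomal protein genes was 11.69, 11.18 and 11.47 on them, against 10.15 to 10.45 on the others. A control probe set for 5S ribosomal RNA read 23.7 and 12.9 on control replicates 1 and 2 and 13.1 on 2 hr replicate 1, against 70.4 to 141.7 on the other 5 arrays. An antisense control probe set, AFFX-CreX-3_st, parted the same arrays, at 9.4, 9.9 and 13 against 53 to 123.6. This grouping was therefore not seen in 5S alone. It was not balanced over the groups, since no 1 hr array read low. The ratio of the 3' to the 5' probe set of actin was 2.88 on control replicate 3 and 1.04 to 1.68 elsewhere, and that of GAPDH 1.56 on it and 0.884 to 1.39 elsewhere. The ratio of hexokinase ran the other way, lowest on control replicate 3 at 1.91 and highest on control replicates 1 and 2 at 3.15 and 6.53.

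**Figure D1:**
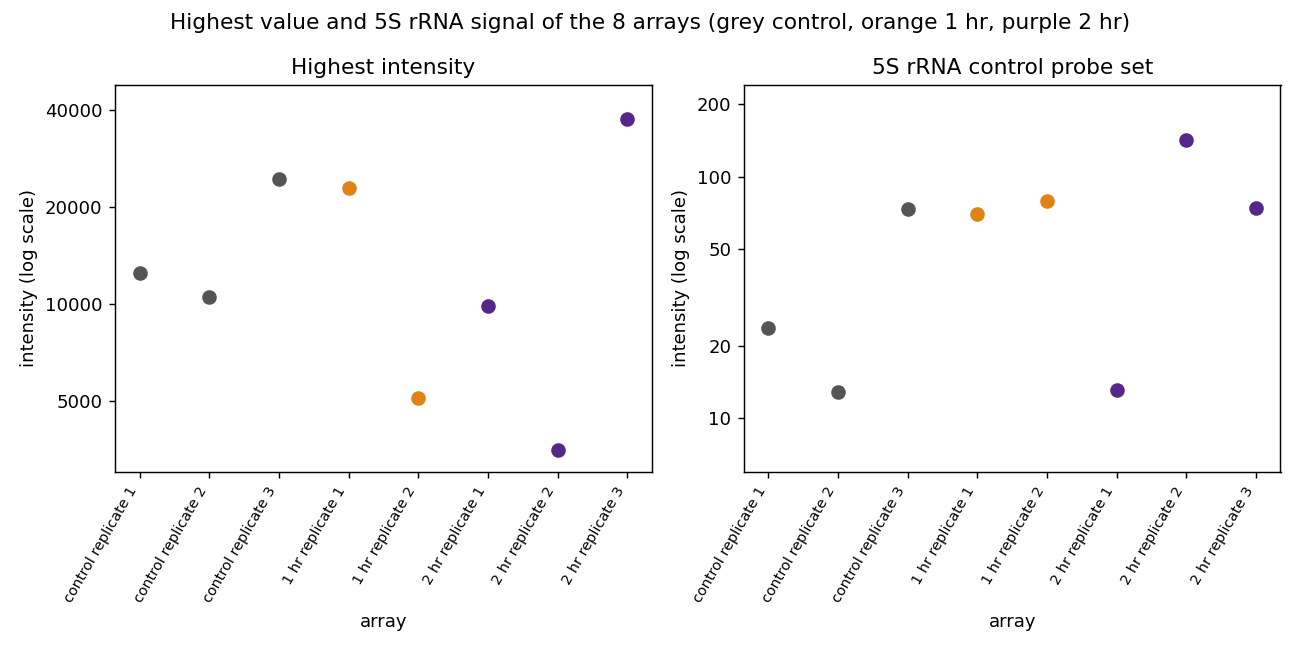
Highest intensity (left) and intensity of the 5S ribosomal RNA control probe set (right) on each of the 8 arrays, on log axes, with points coloured by group. The 3 arrays with a highest intensity of 23009 to 37712 came from 3 different groups, and the 3 arrays with a 5S reading of 12.9 to 23.7 were 2 controls and 1 array of the 2 hr group.

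After 2 hr of isoflurane the glucocorticoid-responsive genes were higher as a group. Of the 30 genes of this list 16 were measured. Of these 14 were higher and 2 lower than in the controls, with a mean log2 change of 0.67 and a median of 0.48. Limma's camera gave the list an adjusted p of 1.32e-08. Of the 10 ways to split the control and 2 hr arrays, 5, the real one among them, gave some list an unadjusted camera p as small. The largest contributions came from Sgk1 (L01624_at), the serum- and glucocorticoid-regulated kinase, at a log2 intensity of 8.48 ± 0.14 (SD, n = 3) against 6.61 ± 0.40 (SD, n = 3) in controls, 3.65-fold higher, and from Gpd1 (AB002558_at), the cytosolic glycerol-3-phosphate dehydrogenase, at 6.85 ± 0.27 (SD, n = 3) against 4.98 ± 0.26 (SD, n = 3), 3.66-fold higher. Errfi1 (rc_AI169756_s_at), an inhibitor of epidermal growth factor receptor signalling, was 2.48-fold higher, with other probe sets at log2 changes of 0.50 and 0.74. Nfkbia (X63594cds_at), the inhibitor that holds NF-kappaB in the cytoplasm, was 1.87-fold higher, and a second probe set read a log2 change of 1.18.

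These 4 genes passed limma's test adjusted over the list alone, with adjusted p of 0.00101 for Sgk1, 0.00377 for Gpd1, 0.0120 for Errfi1 and 0.0161 for Nfkbia, and 0 of the 16 passed over all probe sets. The list shares Nfkbia, Cebpb and Cebpd with the inflammatory list, Dusp1 with the immediate early genes and Slc2a1 with the hypoxia list. The mean of the list was 6.85, 7.001 and 6.59 on the control arrays and 7.49, 7.40 and 7.56 on the 2 hr arrays. The call held with an estimated correlation (limma's camera, adjusted p = 0.0345) and with limma's fry (adjusted p = 0.0143), and over all 22 alternative settings the adjusted p ran from 1.64e-09 to 0.0345. With the 3 arrays of highest top values as a block the camera adjusted p was 2.36e-07, and the 2 hr shift was 0.96 within those arrays (1 against 1) and 0.52 within the others (2 against 2). With the 5S reading as a block it was 2.96e-06, with shifts of 0.56 within the arrays of low 5S reading (1 array against 2 controls) and 0.89 within the others (2 arrays against 1 control).

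**Figure D2:**
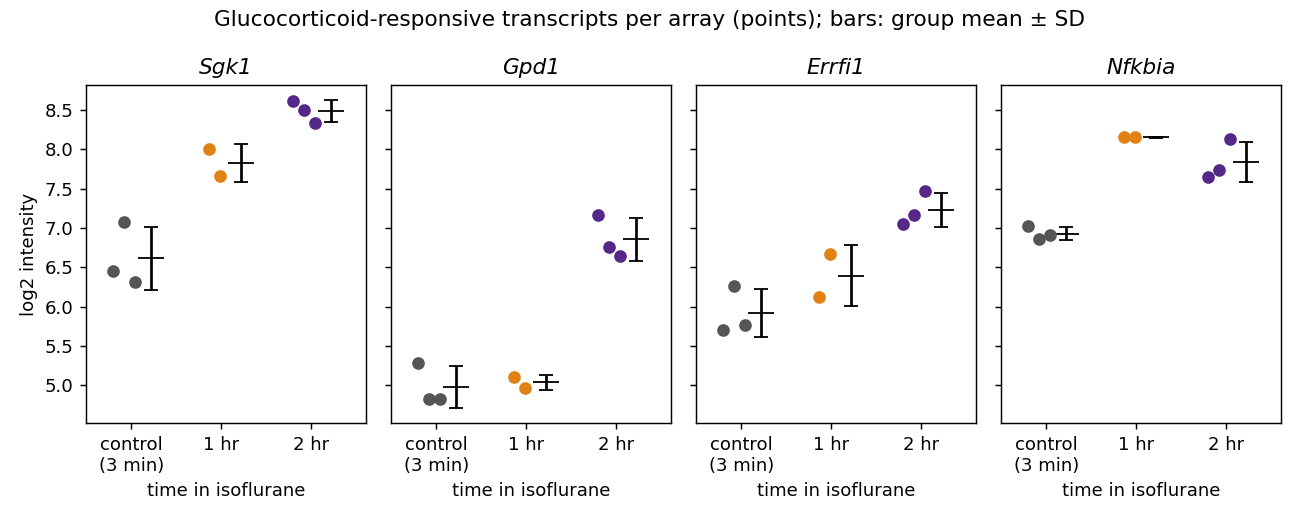
Log2 intensity of Sgk1, Gpd1, Errfi1 and Nfkbia on each array (points) by time in isoflurane, with the group mean and SD beside the points (n = 3 control, 2 after 1 hr, 3 after 2 hr). All 3 arrays of the 2 hr group lay above all 3 controls for each of the 4 genes, and Gpd1 read 5.04 at 1 hr against 6.85 at 2 hr.

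Meningeal and fibroblast markers also passed in this comparison. Of 21 measured genes 17 were higher and 4 lower after 2 hr, with a mean log2 change of 0.35 and a camera adjusted p of 0.00784 (limma). The call was lost with an estimated correlation (adjusted p = 0.674 from limma's camera), with limma's fry (adjusted p = 0.993), and without 2 hr replicate 2 (adjusted p = 0.310), control replicate 3 (adjusted p = 0.0514), the 3 arrays of highest top values (adjusted p = 0.0537) or the 2 arrays of highest Pomc (adjusted p = 0.335), and over 22 alternative settings the adjusted p ran from 0.000349 to 0.993. Col1a2 (rc_AA875531_s_at), a chain of type I collagen, was higher by 0.70 (SE 0.321) and Aldh1a2 (U60063_at), a retinoic acid synthesising enzyme of the meninges, by 1.43 (SE 0.699) on the log2 scale, and neither passed. Both rested in part on control replicate 3, without which Col1a2 was higher by 0.38 and Aldh1a2 by 0.48. With the block of highest top values the camera adjusted p was 0.00473, with shifts of 0.35 within those arrays and 0.34 within the others. With the 5S block it was 0.0116, with shifts of 0.20 and 0.55.

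Single genes did not pass after 2 hr: 0 of 7770 probe sets had an adjusted p under 0.05 in limma, and the smallest adjusted p was 0.492, for Sgk1. At an unadjusted p under 0.05 there were 139 probe sets, 86 higher and 53 lower, against 388.5 that chance alone would give without structure among the arrays. Of the 10 ways to split these 6 arrays, 9, the real one among them, gave at least as many. The highest other gave 1000. The groups did not overlap for 5.44% of probe sets, where chance gives 10%. Among the genes named by the rule, Gm2a (E12286cds_at), the activator protein for ganglioside breakdown, was 5.83-fold higher (SE 0.442 on the log2 scale), Il18 (AJ222813_s_at), a cytokine, 2.84-fold, Slc14a1 (U81518_at), a urea transporter, 2.75-fold and Ucp1 (A04674cds_s_at), the uncoupling protein of brown fat, 2.37-fold. For Il18, Slc14a1 and Ucp1 the controls sat at the floor on 2 of 3 arrays, so these folds depend on the floor. Other probe sets of Il18, Slc14a1 and Ucp1 read log2 changes of 0.06, 0.11 and 0.94. Lower values were read for Gjb5 (rc_AI044985_g_at), a connexin, at a log2 change of -2.07, Map3k1 (U48596_at), a stress-activated kinase, at -1.66, Lep (D45862_g_at), the hormone leptin, at -1.43 and Myh6 (rc_AI104924_f_at), a cardiac myosin, at -1.41. Vom1r93 (U36896_at), a pheromone receptor, sat at the floor on all 3 arrays of the 2 hr group and was at least 2.50-fold lower. Other probe sets of Gjb5 read 0.42 and -0.14, of Map3k1 -0.44 and -0.46, of Lep -0.48 and -0.20, and of Myh6 -0.22. With a higher floor, at the 40th percentile, Gm2a read 1.56, Slc14a1 0.08, Gjb5 -1.25, Map3k1 -0.28, Lep -0.22 and Myh6 -0.12. None of these genes passed the test.

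Among the activity and stress lists, none of the following passed at 2 hr in limma's camera. The immediate early genes had a mean log2 change of -0.13 over 33 genes (adjusted p = 0.0696, and 0.964 with an estimated correlation). Their member Fos, the classic marker of neuronal activation, read -0.79 on its brightest probe set (X06769cds_g_at) and -1.39 and -1.20 on 2 others, and Ccn1 read -0.84. Without control replicate 1 the mean of this list was 0.044, on the other side of 0, and without 2 hr replicate 1 it was -0.035. The list passed without control replicate 3 (adjusted p = 6.56e-05), 2 hr replicate 3 (adjusted p = 0.00264) or the 3 arrays of highest top values (adjusted p = 2.34e-06), with the floor at the 40th percentile (adjusted p = 0.0275) and with the strict filter (adjusted p = 0.0139), within a range of 2.34e-06 to 0.993 over 22 alternative settings. Heat shock proteins and chaperones had a mean of 0.03 (adjusted p = 0.940), with Stip1 at -0.72 and Hspb1 at 0.64. Endoplasmic reticulum stress genes had a mean of -0.02 (adjusted p = 0.706), with Canx at 0.96 and Pdia3 at -0.71. Hypoxia-responsive genes had a mean of 0.10 (adjusted p = 0.721), with Slc2a1, the glucose transporter of the blood-brain barrier, at 0.99 and Adm at least 1.41-fold above controls that sat at the floor. Antioxidant defence genes had a mean of 0.06 (adjusted p = 0.940), with Sod2 at 0.73 and Prdx2 at -0.46. Inflammatory genes had a mean of 0.13 (adjusted p = 0.706), with Nfkbia at 0.91 and C3, the central complement component, at 2.24. Apoptosis regulators had a mean below 0.01 in size (adjusted p = 0.940), with Hrk at 0.71 and Bcl2l11 at -0.43. Circadian clock genes had a mean of 0.17 (adjusted p = 0.260), with Bhlhe41 at 0.76 and Dbp at 0.50, and xenobiotic metabolism genes one of 0.03 (adjusted p = 0.940), with Cyp2d4 at 0.44 and Gstp1 at -0.48. Another probe set had the opposite sign for Hspb1 (-0.46) and Canx (-0.13). Many of these values rested on 1 array. Hspb1 read 0.30, Canx 0.18, Slc2a1 0.47, Sod2 0.35, Bhlhe41 0.31 and Dbp 0.20 without control replicate 3, and Pdia3 -0.36, Hrk 0.40 and Bcl2l11 -0.24 without control replicate 1. Gstp1 read -0.17 without 2 hr replicate 1 and Cyp2d4 0.28 without 2 hr replicate 2, and C3 read 0.84 with the floor at the 40th percentile.

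The families that hold known or proposed targets of volatile anaesthetics did not pass at 2 hr either (limma's camera). GABA and glycine signalling genes had a mean log2 change of 0.07 over 28 genes (adjusted p = 0.803), with Gad2, a GABA-synthesising enzyme, at 1.04 and Gabbr1, a subunit of the GABA-B receptor, at 1.08. Glutamate receptor and transporter genes had a mean of 0.03 (adjusted p = 0.940), with Homer2 at -0.90 and Dlg4 at 0.50. Potassium channel genes had a mean of -0.05 (adjusted p = 0.721), with Kcne1 at -1.04 and Kcns3 at -0.74. Sodium, calcium and HCN channel genes had a mean of -0.13 (adjusted p = 0.312), with Scn11a at -0.98 and Scn4a at -0.98. Monoamine and acetylcholine receptor genes had a mean of -0.04 (adjusted p = 0.706), with Htr4 at -1.39 and Htr1a at -1.10. Synaptic vesicle and release genes had a mean of 0.11 (adjusted p = 0.706), with Syn2 at 0.38 and Rph3a at the floor on all 3 arrays of the 2 hr group, at least 2.16-fold below controls. Neuropeptide genes had a mean of 0.10 (adjusted p = 0.940), with Hcrt at 0.52 and Gnrh1 at -0.998, and G protein and second messenger genes one of 0.08 (adjusted p = 0.706), with Pde4d at 0.89 and Gnb1 at -0.45. Other probe sets had the opposite sign for Gabbr1 (-1.07), Scn4a (0.21 and 0.15), Gnrh1 (0.27) and Gnb1 (0.46). Of the metabolic lists, oxidative phosphorylation genes had a mean of -0.11 (adjusted p = 0.660), with Cyc1 at 0.48 and Atp5f1c at -0.41. Ribosomal protein genes had a mean of -0.17 (adjusted p = 0.260), with Rps29 at -1.54 and Rplp0 at -0.57, which turned to 0.21 for Rps29 and was -0.12 for Rplp0 without 2 hr replicate 2. Cholesterol synthesis genes had a mean of 0.24 (adjusted p = 0.115), with Dhcr7 at 0.89 and Acat2 at 0.49. The cholesterol synthesis genes passed without control replicate 1 (adjusted p = 0.0428) or 2 hr replicate 3 (adjusted p = 0.0184), with the mean of all probe sets (adjusted p = 0.0086) and with the 5S block (adjusted p = 0.0364). Without control replicate 3 their mean was 0.16 (adjusted p = 0.235) and Dhcr7 was higher by 0.42. The same array left out gave -0.43 for Scn11a, -0.63 for Htr1a, 0.29 for Cyc1 and -0.24 for Atp5f1c. Kcne1 read -0.57 and Scn4a -0.53 without 2 hr replicate 2, Gnrh1 -0.66 without 2 hr replicate 3, Rph3a at or below -0.64 without control replicate 1 and Pde4d 0.49 without control replicate 2. With the floor at the 40th percentile Gad2 read 0.13 and Htr4 -0.33. Over all alternative settings Scn11a shrank as far as -0.18, Htr1a -0.19, Gnrh1 -0.18, Kcne1 -0.35 and Pde4d 0.28.

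Markers of the main brain cell types differed little on balance at 2 hr. The mean log2 change was 0.03 for neuron markers (adjusted p = 0.940 in limma's camera), with Camk2a at 0.77 and Ncdn at 0.69, which turned to -0.052 for Ncdn without control replicate 3, and 0.03 for astrocyte markers (adjusted p = 0.721), with Aldh1l1 at 0.76 and Vim at 0.88. It was -0.04 for oligodendrocyte markers (adjusted p = 0.759), with Pllp at -0.26 and Mbp at -0.72, which turned to 0.049 for Mbp without 2 hr replicate 2, and 0.23 for microglia and macrophage markers (adjusted p = 0.535), with Cd74 at 1.80 and Itgam at 0.68. Endothelial and mural cell markers had a mean of -0.01 (adjusted p = 0.940), with Slc2a1 at 0.99 and Cnn1 at -0.98, and blood cell markers one of -0.04 (adjusted p = 0.940), with Cd79b at -0.98 and Cd8a at least 1.48-fold above controls that sat at the floor. Choroid plexus and ependymal markers had a mean of 0.27 (adjusted p = 0.260), with Igfbp2 at 0.60 and Msx1 at 0.66. Pituitary markers had a mean of 0.14 (adjusted p = 0.759), with Fshb at -0.72, where another probe set read 0.31, and Cga at 0.86, and pineal markers one of -0.03 (adjusted p = 0.940), with Cnga3 at -0.72 and Gch1 at -0.36. Of the other lists of this and the 2 preceding paragraphs, the ribosomal protein genes passed without any 1 of the controls or 2 hr replicate 3 and with the 5S block. The neuron markers passed without control replicate 3 or the 3 arrays of highest top values, the endoplasmic reticulum stress and the sodium, calcium and HCN channel genes without control replicate 3, the oxidative phosphorylation genes without 2 hr replicate 3 and the circadian clock genes with the 5S block. The estimated inter-gene correlation was 0.766 for the ribosomal protein genes and 0.275 for the neuron markers, far above the preset 0.01. It was also above the preset for the endoplasmic reticulum stress (0.14), circadian clock (0.131), sodium, calcium and HCN channel (0.119) and oxidative phosphorylation genes (0.045). For the immediate early genes it was 0.0908, for the cholesterol synthesis genes 0.0905, for the pituitary markers 0.0517 and for the meningeal and fibroblast markers 0.0508. Passes of all these lists at the preset, in any comparison, therefore come too easily, most of all for the first 2. For the heat shock, neuropeptide, antioxidant, apoptosis and neuron lists the mean was above 0 while camera's direction, relative to the other genes, was down. Without control replicate 3, Aldh1l1 read 0.39, Vim 0.36, Cd74 0.83, Slc2a1 0.47 and Cnn1 -0.42. Camk2a read 0.36, Cd8a at least 0.061, Igfbp2 0.39 and Cga 0.074 without 2 hr replicate 2, Pllp -0.043 and Cnga3 -0.13 without 2 hr replicate 3, and Fshb -0.44 without control replicate 1. Standard errors of the members named from these lists ran from 0.231 to 1.42 on the log2 scale.

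**Figure D3:**
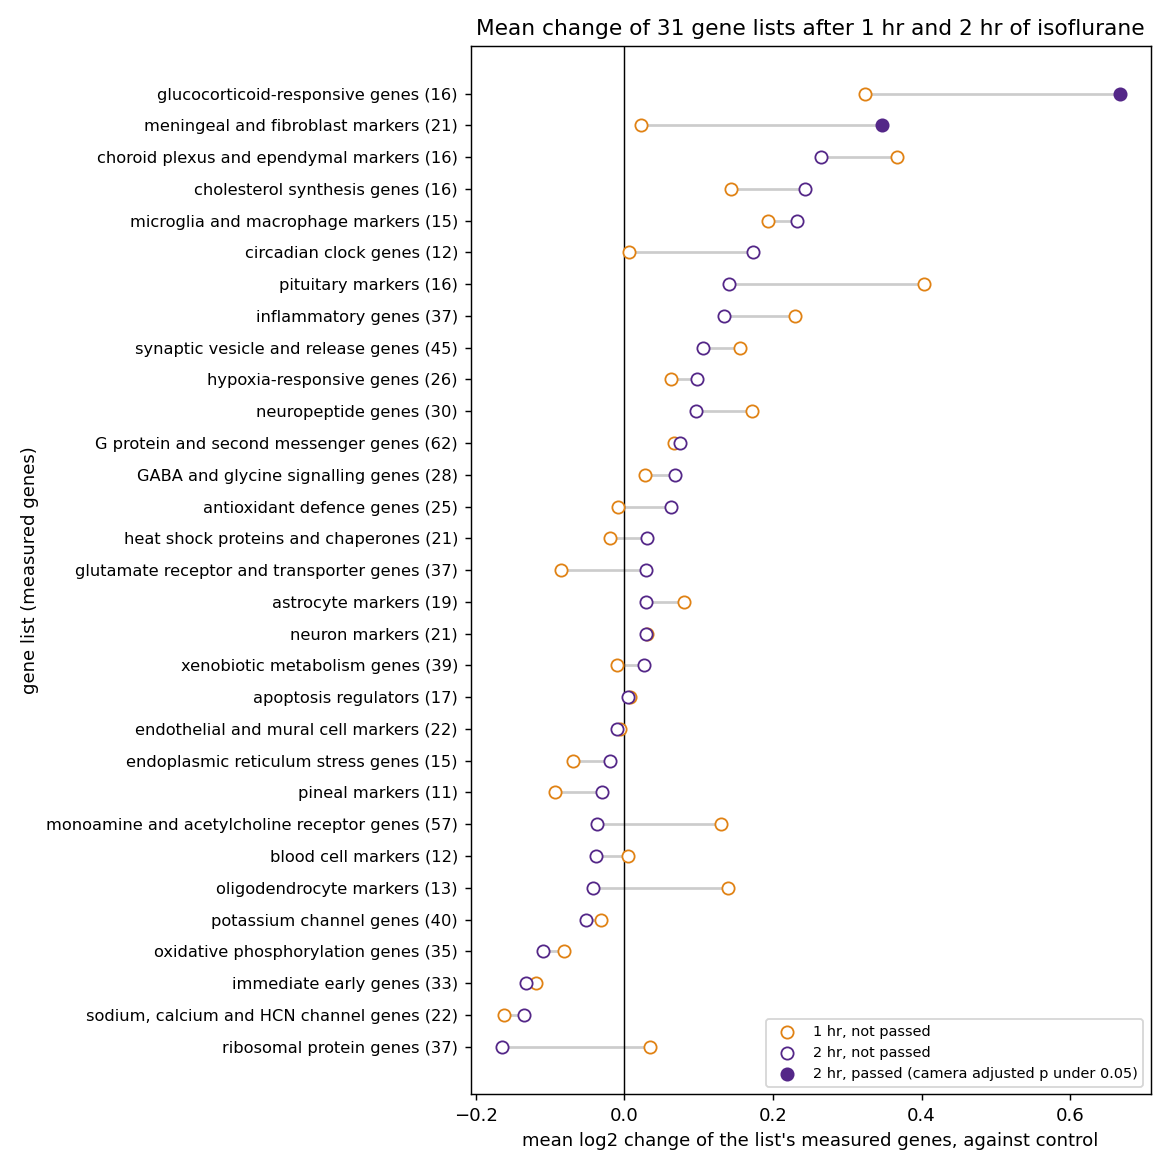
Mean log2 change against control of the measured genes of each of the 31 lists after 1 hr (orange) and 2 hr (purple). Filled points passed limma's camera at the preset correlation. The glucocorticoid-responsive genes stood at 0.32 after 1 hr and 0.67 after 2 hr, the largest mean change of the 31 lists at 2 hr, and the meningeal and fibroblast markers at 0.02 and 0.35.

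After 1 hr of isoflurane, 12 of the 16 glucocorticoid-responsive genes were higher and 4 lower than in the controls, with a mean log2 change of 0.32, and the list did not pass (limma's camera, adjusted p = 0.118). Its members Nfkbia and Sgk1 passed limma's test adjusted over the list alone, with adjusted p of 0.0194 and 0.0249, and 0 members passed over all probe sets. Nfkbia stood at 8.15 ± 0.0043 (SD, n = 2) against 6.93 ± 0.08 (SD, n = 3) in controls, 2.33-fold higher, and Sgk1 at 7.83 ± 0.24 (SD, n = 2) against 6.61, 2.32-fold higher. Gpd1 read a log2 change of 0.06 (SE 0.404). The list passed without control replicate 2 (adjusted p = 0.0266, limma's camera) and 1 hr replicate 1 (adjusted p = 0.0126) and with the 5S block (adjusted p = 0.0338), within a range of 0.0126 to 0.989 over 22 alternative settings. Its mean was 0.21 without control replicate 3. No 1 hr array had a low 5S reading, and control replicate 3 was the only control in the part that held the 1 hr arrays. The pass with the 5S block therefore leans on that array. With the block of highest top values the list's 1 hr shift was 0.50 within those arrays (1 against 1) and 0.26 within the others (1 against 2).

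None of the 31 lists passed after 1 hr in limma's camera, with an estimated correlation or with limma's fry, and 4 had an unadjusted p under 0.05. Leaving out single arrays gave up to 4 lists, the 4 without 1 hr replicate 1. The ribosomal protein genes passed without control replicate 2 or 3 and the neuron markers without control replicate 3. Pituitary markers had a mean log2 change of 0.40, with 12 of 16 genes higher (adjusted p = 0.178, and 0.0126 without 1 hr replicate 1). Without 1 hr replicate 2 their mean was 0.23 (adjusted p = 0.964), and with the strict filter 0.26. Prl (E03166cds_s_at), the hormone prolactin, passed limma's test adjusted over that list alone. Prl stood at 5.57 ± 0.14 (SD, n = 2) against 3.62 ± 0.39 (SD, n = 3) in controls, 3.87-fold higher, and the log2 change was 0.77 with the floor at the 40th percentile. Inflammatory genes had a mean of 0.23, with 26 of 37 higher (adjusted p = 0.292), which was 0.087 without 1 hr replicate 1 (adjusted p = 0.828) and 0.083 with the strict filter. Among them Nfkbia passed limma's test adjusted over the list alone. Immediate early genes had a mean of -0.12 (adjusted p = 0.201), with Ier5 at 2.40, where a second probe set read 0.99, and Klf6 at -1.42, which was -0.14 without 1 hr replicate 1. That list passed without control replicate 3 (adjusted p = 0.00312), and without control replicate 1 its mean was 0.059. Choroid plexus and ependymal markers had a mean of 0.37 (adjusted p = 0.337), with Sostdc1 at 2.03 and Ttr, the thyroid hormone carrier transthyretin, at 2.04, where the log2 intensity of Ttr was 11.53 on 1 hr replicate 2 and 7.42 on 1 hr replicate 1, and without the former Ttr read -0.013. Meningeal and fibroblast markers had a mean of 0.02 (adjusted p = 0.988).

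At 1 hr 0 of 7770 probe sets passed in limma (smallest adjusted p = 0.684, for Mapk8), and 208 had an unadjusted p under 0.05, 142 higher and 66 lower, against 388.5 by chance. The groups did not overlap for 12.7% of probe sets, where chance gives 20%. Without the filter on low values limma passed 4 probe sets, among them Mapk8 and Ldhc. Mapk8 (L27129_at), the stress kinase JNK1, was 4.08-fold higher (SE 0.314 on the log2 scale), with control values near the floor at 3.32 ± 0.23 (SD, n = 3). Other higher values were read for Arl3 (rc_AA799478_at), a small GTPase, at a log2 change of 2.02 (1.17 without 1 hr replicate 1), Dnttip1 at least 3.54-fold and Ldhc, a testis lactate dehydrogenase, at least 2.05-fold above controls that sat at the floor. Lower values were read for Maf (U56242_at), a transcription factor, at -2.19, Alox15, a lipoxygenase, at -1.94, Tmem69 at -1.89, Ctla4, an inhibitory receptor of T cells, at -1.60 and Ugt2b35 at -1.59. Thrb, a thyroid hormone receptor, sat at the floor on both 1 hr arrays, at least 2.76-fold below controls. Other probe sets disagreed, with readings of -0.46 and 1.26 for Maf, -0.18 for Arl3 and 0.11 for Ctla4. With the floor at the 40th percentile Mapk8 read 0.54 and Maf -0.70. Over 23 alternative settings Thrb ran from -2.51 to -0.022. None of the genes named in this paragraph passed with the filter in place.

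Over both exposures together, the glucocorticoid-responsive genes were higher by a mean of 0.50 on the log2 scale, with 12 of 16 genes higher, and passed limma's camera (adjusted p = 3.67e-06). The call was lost with an estimated correlation (adjusted p = 0.0726 from limma's camera) and held with limma's fry (adjusted p = 0.0396), within a range of 1.48e-06 to 0.0726 over 22 alternative settings. Sgk1 rose 2.91-fold and Nfkbia 2.09-fold in limma's test adjusted over the list alone (adjusted p = 0.00204 and 0.00568), and 0 members passed over all probe sets. The list means of all 5 exposed arrays, 7.09 to 7.56, lay above all 3 controls. An exact two-sided permutation test of these 8 means over 56 splits gave p = 0.0357, or 0.831 after adjustment over the 31 lists. With so few splits no single list could pass that adjustment on its own.

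The immediate early genes fell on balance by a mean of 0.13 on the log2 scale over 33 genes in the same comparison and passed narrowly (limma's camera, adjusted p = 0.0495). The call was lost with an estimated correlation (adjusted p = 0.908 from limma's camera), with limma's fry (adjusted p = 0.997) and without control replicate 1, where the mean was 0.052 (adjusted p = 0.914). It was also lost without control replicate 2 (adjusted p = 0.185), 1 hr replicate 1 (0.129), 1 hr replicate 2 (0.168), 2 hr replicate 1 (0.287) or 2 hr replicate 2 (0.247), and 6 of 22 alternative settings kept it. Members went both ways, with Fos at -0.67 (SE 0.222) and Ier5 at 1.98 (SE 0.539), and 0 passed adjusted over all probe sets or over the list alone. Within the 3 arrays of highest top values the shifts of this list were 0.19 at 1 hr and 0.40 at 2 hr, and within the other 5 they were -0.25 and -0.40. Sodium, calcium and HCN channel genes (mean -0.15, with Scn4a at -0.83 and Scn2a at -0.65), choroid plexus and ependymal markers (mean 0.32, with Sostdc1 at 1.26 and Msx1 at 0.68) and pituitary markers (mean 0.27, with Prl at 0.85 and Trhr at 0.61) each had an adjusted p of 0.196 in limma's camera, and without 1 hr replicate 1 they passed with 0.0259, 0.0130 and 0.0452. Without 1 hr replicate 2 the means of the first 2 were -0.016 and 0.20 (adjusted p = 0.798 and 0.946), and without 2 hr replicate 2 that of the pituitary markers was 0.13 (adjusted p = 0.602). Without both of these arrays, those of highest Pomc, the channel genes stood at 0.043, on the other side of 0, the choroid plexus markers at 0.14 and the pituitary markers at 0.045. Without the 3 arrays of highest top values the channel genes and the choroid plexus markers passed (adjusted p = 0.0033 and 0.0053). The ribosomal protein genes passed without control replicate 2 or 3 or 2 hr replicate 3, and the neuron markers without control replicate 3. Leaving out 1 array brought Scn4a to -0.39 (1 hr replicate 2), Scn2a to -0.40 and Sostdc1 to 0.67 (control replicate 1), and Trhr to 0.31 (control replicate 2). Another probe set of Trhr read -0.06 and others of Scn4a 0.17 and below 0.01 in size.

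Single genes did not pass for any exposure (0 of 7770 in limma, smallest adjusted p = 0.989). At an unadjusted p under 0.05 there were 172 probe sets, 116 higher and 56 lower, and exposed and control arrays did not overlap for 1.93%, where chance gives 3.57%. Of 100 assignments of the arrays to groups, 88, the real one among them, gave at least 172. The highest other gave 1650. Besides Sgk1 and Nfkbia, the genes that the rule named by unadjusted p among those without overlap were, on the higher side, Tns2 (log2 change 1.78), Slc14a1 (1.46), Gad2 (1.25) and Dcaf7, which was at least 1.93-fold above controls at the floor. On the lower side they were Ugt2b35 (-1.43), Myh6 (-1.42), Map3k1 (-1.40), Maf (-1.37), Lep (-1.32) and Vom1r93 (-1.21). Other probe sets read 0.12 for Slc14a1, -0.25 for Myh6, -0.05 and -0.38 for Map3k1, -0.20 and 0.70 for Maf, and -0.34 and below 0.01 in size for Lep. With the floor at the 40th percentile Tns2 read 0.98, Slc14a1 0.09, Gad2 0.32, Myh6 -0.12, Map3k1 -0.28, Maf -0.62 and Lep -0.22.

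Between 2 hr and 1 hr, Gpd1 was higher at 2 hr by 1.82 on the log2 scale (SE 0.404), 3.52-fold, and passed limma's test adjusted over the glucocorticoid-responsive list alone (adjusted p = 0.0206). Prl was lower at 2 hr by a log2 change of -2.19 (SE 0.388), and passed adjusted over the pituitary markers alone (limma, adjusted p = 0.0039). Prl sat at the floor on 2 of the 3 arrays of the 2 hr group, so the size depends on the floor, and over 23 alternative settings it ran from -3.15 to -0.77. Over all probe sets 0 of 7770 passed in limma (smallest adjusted p = 0.411, for Mapk8), and 215 had an unadjusted p under 0.05, 72 higher and 143 lower. Without the filter on low values 4 passed. The groups did not overlap for 13.8% of probe sets, where chance gives 20%. None of the 31 lists passed, and the ribosomal protein genes passed only without 2 hr replicate 3 and the pituitary markers only without 2 hr replicate 2 when single arrays were left out. The glucocorticoid-responsive genes (mean log2 difference 0.34) and the meningeal and fibroblast markers (0.32) each had an adjusted p of 0.0581 in limma's camera, and 0.824 and 0.985 with an estimated correlation. Both lists passed without control replicate 3 (adjusted p = 0.0271 for each, limma's camera), with median centring and with the strict filter, the first also without 2 hr replicate 2 (adjusted p = 0.0250) and the second without 2 hr replicate 3 (adjusted p = 0.0265). The mean of the meningeal and fibroblast markers was 0.21 without 1 hr replicate 2 (adjusted p = 0.673) or 2 hr replicate 2 (adjusted p = 0.260), and 0.20 with the mean of all probe sets. Over 22 alternative settings the adjusted p ran from 0.00957 to 0.824 for the first and from 0.00909 to 0.9996 for the second. Their means ran from 0.25 to 0.46 and from 0.099 to 0.52.

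Higher values at 2 hr than at 1 hr were read for Alox15 (log2 difference 2.17), Gm2a (2.10), Maf (1.65), Ucp1 (1.41) and Il18 (1.33). Lower values were read for Vps26a (-1.97) and Bcl2l11 (-1.68), and Mapk8, Abcb11 and Ldhc, all at the floor on the 2 hr arrays, were at least 4.47-fold, 4.01-fold and 2.05-fold lower. Other probe sets read -0.10 for Il18, 1.61 for Ucp1, 0.52 and -1.13 for Maf, and 0.19 and -0.39 for Bcl2l11. With the floor at the 40th percentile Maf read 0.16 and Vps26a -0.57. None of these genes passed over all probe sets with the filter in place.

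The 1 hr and 2 hr effects were compared across the 7770 probe sets, which are not independent replicates. Their Pearson correlation was 0.42. In 1000 simulations of unchanged groups against the same 3 controls it was 0.45 on average, from 0.41 to 0.49. The observed covariance of 0.0837 lay below the simulated mean of 0.133 and below the whole simulated range of 0.118 to 0.151. The correlation was therefore no larger than in these simulations. They drew each probe set independently and left out the floor and any structure shared across probe sets. They therefore do not decide how much the shared controls gave. Leaving out 1 array at a time gave correlations from 0.15 (without 1 hr replicate 2) to 0.58. Among probe sets with an unadjusted p under 0.05 in both comparisons, 16 were higher in both and 11 lower in both, where independent lists of these sizes would share 1.57 and 0.45. Part or all of that excess may come from the shared controls, since no overlap was simulated with them. The 3 controls are too few to be divided between the comparisons.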

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

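The tests of array blocks, of control replicate 3, of carried-along pituitary or meningeal tissue, of a single array, of exposure length and of the number of genes in other splits were chosen only after the result was seen.

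Gpd1 read higher at 2 hr than at 1 hr, and passed only within its own list. Its effect at 2 hr minus its effect at 1 hr was 1.82 on the log2 scale (limma, adjusted p = 0.0206 adjusted over the list alone, and 0 genes over all probe sets, with 215 at an unadjusted p under 0.05). Prl differed the other way, by -2.19 (limma, adjusted p = 0.0039 adjusted over the list alone), a size that depends on the floor (-0.77 with the floor at the 40th percentile). An antisense control probe set, AFFX-BioB-M_st, which the gene comparisons leave out, read 22.8 on the lowest exposed array and 37.4 on the highest, against 8.6, 17.3 and 20.7 on the controls. These readings all lay below the lowest array median of 41.4, and they are not a measure of the spike-in itself. This probe set was 1 of 59 control probe sets with every exposed array above every control, where chance puts 1.79% of them that way, about the share seen.

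The glucocorticoid-responsive genes were higher after 2 hr by a mean of 0.67. As the whole cause, the tables argue against the arrays with the highest top values, since the shift was 0.96 within them and 0.52 within the others. Each group held 1 of these arrays, so a block of them could not move the mean. Its camera adjusted p of 2.36e-07 therefore does not test this cause. Taken alone, the grouping seen in the 5S control probe set is also argued against (camera adjusted p 2.96e-06 as a block), with shifts of 0.56 and 0.89 in its 2 parts. The same holds for control replicate 3 alone, whose actin 3'/5' ratio was the highest and hexokinase ratio the lowest (6.2e-06 without it). It also holds for carried-along pituitary tissue (1.07e-07 without the 2 arrays of highest Pomc). Control replicate 3 was the only control without a low 5S reading. The 5S grouping and that array together are therefore tested by 2 hr replicate 1 alone, and their combination stays open. These camera p-values do not measure the spread between samples. Whether the longer exposure matters stays open, since 2 hr against 1 hr gave a camera adjusted p of 0.0581. The groups differ in time under isoflurane, and time intubated and handled goes with it, so the design does not separate these, and whether a hormone response lay behind the list was not tested. The saline perfusion that the labels mention for the controls alone is a further open explanation that was not tested.

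Splits of the arrays set limits on these calls. For 2 hr against control the 10 splits are too few for a share under 0.05: the list's own camera p was 4.27e-10 in 1 of 10 splits, and the smallest in the other splits was 0.00305. Some list of the 31 had a camera p as small in 5 of 10 splits, the real one among them, down to 2.41e-23. For any exposure 3 of 100 assignments, the real one among them, gave the list a camera p as small as 1.18e-07, the smallest other being 4.06e-08. One of these 3 kept the controls and regrouped the exposed arrays, and one set the 2 hr arrays apart. The list was singled out from 31, and 30 of 100 assignments gave some list a p as small, down to 2.01e-24, so chance cannot be excluded for the strongest of 31 lists. For the number of lists, 2 were called, as many were called in 68 of 100 assignments (highest other 6), so chance cannot be excluded for that number. In the 2 hr comparison 8 of 10 splits called as many as the real 2, the highest other being 7, in 2 splits, one of them with control replicates 1 and 2 and 2 hr replicate 1, the low-5S arrays, on one side. Genes called were 0, so all 10 of 10 and 100 of 100 gave as many, the highest other being 0 and 118. The 118 came with the arrays of highest top values (control replicate 3, 1 hr replicate 1 and 2 hr replicate 3) on one side, which points to a structure of the samples larger than the exposure. With that structure as a block 0 genes passed in each comparison (limma).

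Meningeal and fibroblast markers were higher after 2 hr by a mean of 0.35. More meningeal tissue in the 2 hr samples stays open, since the 10 most abundant members had a median log2 change of 0.394 against 0.356 for the list. The most abundant of them, Ptgds and Igf2, read -0.02 and 0.08. Without 2 hr replicate 2 the adjusted p was 0.310, but the mean was still 0.23 and the list means of the other 2 hr arrays, 6.94 and 6.842, lay above the controls at 6.488 to 6.816, so the share of that array in the pattern stays undecided. The exposure itself was not separated from these and stays open.

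Pituitary hormone transcripts were high on an array of each exposed group. On 1 hr replicate 2, Gh1 lay 2.46 above its mean on the other arrays, with Prl 1.89 and Pomc 1.84 above, whereas Cga (-0.118), Lhb (-0.0705) and Tshb (0.316) did not stand out, so carried-along anterior pituitary tissue may explain the first 3 and stays open. On 2 hr replicate 2, Pomc lay 2.32, Cga 2.36 and Tshb 2.41 above, and the receptor transcript Drd2 3.2 above. Gh1 lay at -0.719 and Prl at -0.29 on it, which argues against tissue of the whole anterior lobe there. A part of the gland poor in both stays open. Oxt (10.63) and Gal (5.998) were also highest on this array, so whether the pattern is confined to the gland was not settled. Prl was also high on 1 hr replicate 1 (5.476), so that tissue on 1 array does not account for the whole Prl difference. No biological explanation was tested for these arrays.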

How the results depend on the processing

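The tests with array blocks, without the arrays of highest top values, without the arrays of highest Pomc and without the pituitary markers were chosen only after the result was seen.

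The glucocorticoid-responsive genes at 2 hr passed in all 22 alternatives run (mean 0.52 to 0.76, adjusted p 1.64e-09 to 0.0345), and for any exposure in 21 of 22. The exception was the estimated correlation, with a mean of 0.50 and an adjusted p of 0.0726. The number of genes called by limma stayed 0 in all comparisons and alternatives except without a filter, with 4 for 1 hr against control (lowest adjusted p 0.0292) and 4 for 2 hr against 1 hr (0.0286). Signals near the floor of 3.19 and the number of arrays limit what could be seen. Where an array left out leaves 1 in a group, that array is assumed to vary like the others. The fit of only the groups compared was not run for any exposure, where it equals the fit of all groups. The cause was not tested for any of the changes below.

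Lists called for any exposure, 2 in the fit reported, were 1 with quantile normalization, median centring, no filter, fry, the mean of all probe sets or the arrays of highest Pomc left out, 0 with the estimated correlation, and 5 with the control probe block or with the long upper tail arrays left out. At 2 hr, 2 in the fit reported, they were 1 with the estimated correlation, fry or the arrays of highest Pomc left out, 5 with the control probe block, and 3 with the floor at the 40th percentile or the strict filter (immediate early genes added), the mean of all probe sets (cholesterol synthesis genes added) or the long upper tail arrays left out. At 1 hr, 0 in the fit reported, they were 5 with the control probe block and 2 with the long upper tail arrays left out. For 2 hr against 1 hr, 0 in the fit reported, they were 2 with median centring, the strict filter or the long upper tail arrays left out, and 1 with the floor at the 40th percentile or the mean of all probe sets. Leaving out 1 array at a time gave 1 to 4 lists for any exposure (4 without control replicate 3 or 1 hr replicate 1), 1 to 6 at 2 hr (1 without 2 hr replicate 2, 6 without control replicate 3 or 2 hr replicate 3), 0 to 4 at 1 hr (4 without 1 hr replicate 1) and 0 to 2 for 2 hr against 1 hr.

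With the control probe block the glucocorticoid-responsive genes passed at 1 hr (mean 0.44, camera adjusted p 0.0338). Control replicate 3 was the only control in the part of that block that held the 1 hr arrays. Leaving out 1 array gave these genes means of 0.21 to 0.42. For 2 hr against 1 hr they passed with median centring (0.37), the floor at the 40th percentile (0.38), the strict filter (0.36) and the mean of all probe sets (0.37), and leaving out 1 array gave 0.29 to 0.39. The immediate early genes were reversed without control replicate 1, and leaving out 1 array gave -0.30 to 0.059 at 1 hr, -0.31 to 0.044 at 2 hr and -0.30 to 0.052 for any exposure. With the arrays of highest Pomc left out, the sodium, calcium and HCN channel genes were reversed for any exposure (0.043), and the pituitary markers (0.045) reversed camera's direction. Of the list members named, reversed were Ncdn without control replicate 3 (-0.052) or the long upper tail arrays (-0.095), Pllp without the latter (0.0056), and Rps29 (0.21) and Mbp (0.049) at 2 hr and Ttr (-0.013) at 1 hr without replicate 2 of that group or the arrays of highest Pomc. At the other end, leaving out 1 array gave 1.10 for Ncdn, -2.86 for Rps29, -1.13 for Mbp and 4.10 for Ttr. The correlation of the 1 hr and 2 hr effects ran from 0.15 to 0.65 over 20 alternatives.

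The replicate numbers do not pair the samples: deviations of arrays with the same number correlated across genes from -0.331 to 0.286. With the replicate number as a block, 0 genes passed, and lists called were 1 at 1 hr (ribosomal protein genes), 1 for any exposure and 2 for 2 hr against 1 hr (ribosomal protein genes and, with an adjusted p of 0.00909, meningeal and fibroblast markers).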

Other observations

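None of the values in this part has a test of its own beyond those named, and all of the permutation tests were chosen only after the result was seen.

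Single arrays stood apart for single genes. The log2 intensity of Ttr was 11.53 on 1 hr replicate 2 and 6.918 to 8.271 on the other 7 arrays. On 2 hr replicate 2 Oxt read 10.63 and Gal 5.998, against 3.548 to 7.26 and 3.186 to 3.379 elsewhere. Pmch read 9.58 on 1 hr replicate 1 and 3.186 to 4.42 elsewhere. Aldh1a2, a member of the meningeal list, read 3.263 on control replicate 3. C3 stood at the floor of 3.19 on control replicates 1 and 3 and on 1 hr replicate 1, at 3.838 on control replicate 2, at 5.909 on 1 hr replicate 2 and at 6.077, 5.789 and 5.066 on the 2 hr arrays.

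The means of the inflammatory list and of the choroid plexus and ependymal list were higher on all 5 exposed arrays than on all 3 controls. Exact two-sided permutation p-values were 0.0536 and 0.0893, or 0.831 and 0.923 after adjustment over 31 lists, so neither passed. The splits are too few for a single list to pass that adjustment on its own.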
